A study of Caenorhabditis elegans with 2 samples.

How the data were processed

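The samples were 2 ChIP-seq libraries of whole C. elegans L1 larvae of 1 group, with a GFP-tagged EGL-13, biological replicates 3 and 4 per the labels. Per the labels, chromatin was sheared by sonication and precipitated with an anti-GFP antibody. The authors deposited region lists in narrowPeak format on ce10 and ce11: 1 list per replicate and 1 of both replicates pooled, each of 30000 regions that include background and served as input to IDR (a measure of reproducibility between ranked lists), and 1 optimal list after an IDR threshold. A control alignment was used by the authors in making the lists, per the deposited file descriptions. The peak caller, aligner and IDR threshold are not given in the sources used here. The lists were used as the authors called them, per replicate and on pooled reads.

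Each region has a signal value from the authors' peak caller, whose scale is not given. It was used here to rank regions within a list, to correlate the replicates (by rank and on the log2 scale) and to compare builds. The −log10 q value deposited with each region was tied at its maximum of 3.36 for 1134 of the optimal peaks and was not used to rank. The summit offset deposited with each region gave the summit. All 2294 optimal regions were identical to pooled regions and were the 2294 strongest of them, so a site can owe its place to the pooled reads with little support from 1 replicate. Read counts and library sizes were not used here, so depth per sample is unknown and intervals cover counting of sites or genes only.

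The chromosome names of the ce11 lists matched the WBcel235 genome, which is ce11, and all regions lay within its chromosome lengths. Genes came from Ensembl release 115 and tests ran over 19865 protein-coding gene names on the nuclear chromosomes. Coordinates were not converted between builds, and ce10 lists were used only for counts, signal values, replicate agreement and the share on X. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 1.

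Replicate agreement compared the 2294 strongest regions of each replicate, with summits within 100 bp counted as shared and 1000 circular shifts as chance. Summits were classed as promoter (1000 bp upstream to 200 bp downstream of a protein-coding 5′ end), then exon, intron or intergenic. Gene lists were tested with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over 25 lists, which is an adjustment over the lists alone, and name classes of at least 15 genes were adjusted over all classes scanned. A site in the promoter windows of several genes counted for each, so genes that share a site are not independent in this test. Motifs were searched on both strands within 50 bp of the summit and in windows centred 300 bp to each side, with an exact McNemar test against 1 side drawn at random. Summit-to-flank ratios of hexamers had 0.5 sites added to each count. Fixed motifs were adjusted over 9 and hexamers over 2080. Weaker regions were drawn from 27332 pooled regions that no optimal peak overlaps. Intervals are at the 95% level.

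Genes were named by a rule fixed before the data were examined: egl-13; the genes of the 20 strongest optimal sites; in each list the 4 members with the strongest site; and the genes of the 5 strongest pooled regions outside the optimal list. Genes are those with the summit in the promoter window, else the gene that holds it, else the nearest 5′ end. Lists, tests and most alternatives were also set before the data were examined. Alternatives covered the summit distance, promoter window, background, null, threshold, build and the use of each replicate alone; those added later were the sites found in the top of both replicates, matching on GC content, leaving out sites near tRNA, snoRNA or snRNA genes, the replicate correlation over all pooled regions, and the weaker-region comparison in each replicate alone.

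The statistics were tested on simulated data. A planted share of 60% of common sites among 2294 was recovered as 60.1%. Sites planted at 40% of ribosomal protein genes were recovered as 43.8% with 0 other lists called. AACAAT was planted at part of 2294 random summits, so that 30.2% were expected to hold it with the background share included, and 30.5% did. The background share came from the same sequences, so the last comparison checks the counting only. Signal tracks and alignments were not used here. Names in the fixed lists that belong to microRNAs were not in the tests of protein-coding genes.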

Results

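EGL-13 is a SoxD-type HMG-box transcription factor of Caenorhabditis elegans, known from textbook genetics for roles in the cell fate of the BAG and URX gas-sensing neurons and of the uterine cells that connect to the vulva. Chromatin immunoprecipitation with an anti-GFP antibody followed by sequencing was done on whole hermaphrodite L1 larvae of strain GOU883, in which EGL-13 carries a C-terminal GFP-FLAG tag, 6 h after synchronization by starvation. There were 2 biological replicates, numbered 3 and 4, in 1 group, so the study describes where the tagged factor was recovered and contrasts no conditions. The read depth of each library is unknown from the files used here. The precision of a site can be judged only from its recovery in each replicate, and not every site was recovered in both. Positions are 1-based on ce11.

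The deposited list of reproducible (optimal) peaks held 2294 regions with a median width of 384 bp. Their signal values, given by the authors' peak caller, ran from 65.3 to 975. The strongest site lay on chromosome V between 1151310 and 1151685, between genes, with the 5′ end of cmd-1, the calmodulin gene, as the nearest at 4782 bp and linc-128, a long noncoding RNA gene, within 200 bp. The next lay 292 bp upstream of rpl-3 (WBGene00004414, large ribosomal subunit protein), at III:3867432-3867706, with a signal value of 949. Among the 20 strongest sites, 4 lay at ribosomal protein genes (rpl-3, rpl-20, rpl-15 and rpl-35) and 2 at chaperone genes, hsp-60 and hsp-1, which encode a mitochondrial and a cytosolic chaperone. Others lay 32 bp upstream of tasp-1 (and 753 bp upstream of K01G5.10), 157 bp upstream of cdc-48.1, which encodes a AAA ATPase of protein quality control, and 90 bp upstream of tos-1. The site assigned to cux-7, lig-4 and C07H6.2 lay in the 5′ UTR of cux-7. The other promoter sites of this group were those of egg-5, nhl-2 with tag-340, H41C03.3 and nspc-17, and Y17G9B.5, K11H12.8 and Y22D7AL.10 shared the sites of rpl-20, rpl-15 and hsp-60. The egg-5 and H41C03.3 summits, 589 and 959 bp upstream, also lay within 200 bp of the snRNA genes sls-2.4 and sls-2.1. Other noncoding RNA genes lay within 200 bp of the egg-5, nhl-2 and hsp-1 summits. Of these 20 sites, 14 had a promoter window at the summit, 2 lay in introns (of Y56A3A.7 and Y41G9A.17) and 4 were assigned to the nearest 5′ end (cmd-1, F20B6.9, sup-26 and ZK899.6). Their lowest rank was 32 in replicate 3 and 42 in replicate 4. The 5 strongest pooled regions outside the optimal list were those of ZC455.1, pqn-39, T12A7.2, C29F3.7 and the golg-2 and F33G12.7 pair, with signal values from 65.2 to 65.3.

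The replicates were compared to ask whether they recovered the same places. Of the 2294 strongest regions of replicate 3, 1469 (64%) had a summit within 100 bp of one of the 2294 strongest of replicate 4, and the reverse share was the same. Circular shifts of the summits within each chromosome gave 0.486% on average and at most 1.09% (one-sided circular-shift permutation p = 0.001, the smallest that 1000 shifts can give). Among the optimal peaks, 1487 (64.8%) were among the strongest regions of both replicates, 492 of replicate 3 only, 252 of replicate 4 only and 63 of neither. At the 2146 optimal peaks with a summit in both lists, signal values correlated across sites with Spearman's rho = 0.625 and Pearson's r = 0.710 on the log2 scale (permutation p = 1e-05 for each, the smallest that 100000 pairings can give). Without the 2 sites farthest from the median of replicate 3, r was 0.707. Sites are not independent replicates.

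**Figure D1:**
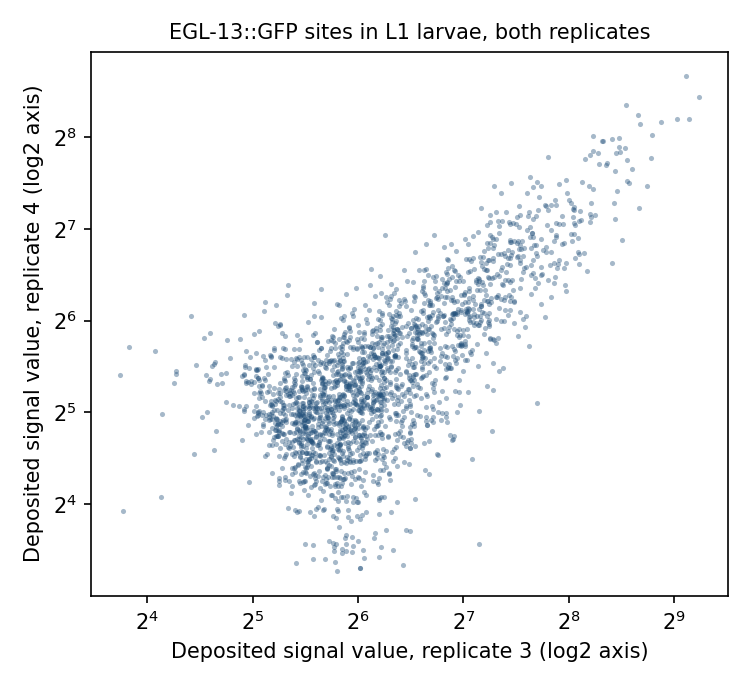
Deposited signal value of each of 2146 optimal peaks in replicate 3 (x axis, log2 scale) and replicate 4 (y axis, log2 scale), with 1 point per peak. Points rise together, with Pearson's r = 0.710, and scatter most at low signal.

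Sites lay at promoters far more often than shifted summits did. The window from 1000 bp upstream to 200 bp downstream of a protein-coding 5′ end held 1303 summits (56.8%, 95% Wilson interval 54.8 to 58.8), against 25.7% of shifted summits. Exons held 45 summits (1.96%, against 21.6%) and introns 366 (16%, against 27.6%), both lower. All 3 differences had an adjusted two-sided circular-shift permutation p = 0.00267, from the smallest p of 0.002 that the shifts can give. Intergenic summits, 580 (25.3%), did not differ past the threshold from the 25% of shifted summits (adjusted permutation p = 0.811). All these shares are of all summits, and promoter was assigned first, so the promoter excess lowers the shares of the other classes. Outside promoters, intergenic summits (580) outnumbered intron summits (366), whereas shifted summits had similar shares of both (25% and 27.6%). Shares among the summits outside promoters were not tested. The ratio of observed to shifted intergenic summits fell to 0.843, past the threshold, in the stronger 50% of sites and rose to 1.10, past the threshold, with a promoter window of 500 bp.

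Sites were unevenly spread over the chromosomes. Chromosome X held 491 of the 2294 sites (21.4%, exact 95% interval 19.7 to 23.1), more than its 17.7% of the length of the nuclear chromosomes (exact binomial p = 4.75e-06, adjusted p = 4.75e-06). Chromosome III had 28.1 sites per Mb, X 27.7, I 25.7, II 23.2, IV 20.6 and V 15, so X was not the densest. Of 1803 autosomal sites, 1106 (61.3%, exact 95% interval 59.0 to 63.6) lay in the central 50% of a chromosome (adjusted p = 9.83e-22), where C. elegans autosomes hold many widely expressed genes. The X excess was no longer past the threshold in the stronger 50% of sites (19.5%, exact binomial p = 0.104).

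With the main promoter window, ribosomal protein genes carried sites most often of the 25 fixed gene lists. A site lay in the promoter window of 44 of 80 (55.0%), against 8.27% of all other protein-coding genes (odds ratio 13.5, 95% interval 8.49 to 21.7, Fisher's exact adjusted p = 1.67e-25), and 37 of the 80 had one among the strongest of both replicates. The odds ratio fell to 6.14 against genes with any pooled region and to 4.87, with 27 genes, when each site went to its nearest 5′ end. Under that assignment they ranked below the pan-neuronal genes (17 of 24) and the gas-sensing neuron genes (8 of 18), and with a 2000 bp window (46 of 80) below the pan-neuronal genes (14 of 24). Vacuolar ATPase and mitochondrial respiratory genes carried sites in 12 of 40 cases (odds ratio 4.66, Fisher's exact adjusted p = 3.85e-04), among them atp-1, atp-2, vha-12 and cox-14, with an odds ratio of 2.75 under nearest assignment. Their count was 10.3 times the mean of shifted summits. That is a lower baseline than other genes, since promoters as a whole held 2.21 times the share of shifted summits. The atp-1 summit lay 8 bp upstream of its 5′ end.

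Pan-neuronal genes, many of which encode synaptic or neuropeptide-processing proteins, carried sites in 11 of 24 cases (odds ratio 9.21, 95% interval 3.73 to 22.3, Fisher's exact adjusted p = 1.14e-05). The strongest were egl-21, rgef-1, maco-1 and rab-3, with signal values of 181, 170, 135 and 115. The rab-3 site, in an intron, had no replicate 4 summit within 100 bp; the other 10 genes had a site among the strongest of both replicates. The odds ratio of this list was 4.63 with a 500 bp window (6 genes), 4.52 against genes with any pooled region and 23.1 with assignment to the nearest 5′ end (17 genes). Genes of the BAG and URX gas-sensing neurons carried sites in 8 of 18 cases (odds ratio 8.69, 95% interval 2.98 to 24.5, Fisher's exact adjusted p = 3.26e-04). The strongest were gcy-33, which encodes a soluble guanylate cyclase, flp-17, which encodes a neuropeptide, aha-1 and gcy-36, with signal values of 223, 100, 91.4 and 84.5. The call on this list ended in the stronger 50% of sites, where 1 gene was left (Fisher's exact adjusted p = 0.906), and with sites found in the top of both replicates, an alternative chosen after seeing the data, where 4 were left (odds ratio 4.51, adjusted p = 0.0550). Against genes with any pooled region its odds ratio was 4.11. The flp-17 site had no replicate 4 summit within 100 bp.

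The gcy-33 site spanned V:12001906-12002289, 301 bp upstream of the 5′ end of gcy-33 (WBGene00001553, V:11995805-12001797, minus strand), between genes. It ranked 319 in replicate 3 and 261 in replicate 4. The 51 bp around its summit, V:12002073-12002123, read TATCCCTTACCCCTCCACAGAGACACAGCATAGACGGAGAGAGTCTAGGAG. A tRNA gene at V:12002176-12002260 lay inside the same region.

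**Figure D2:**
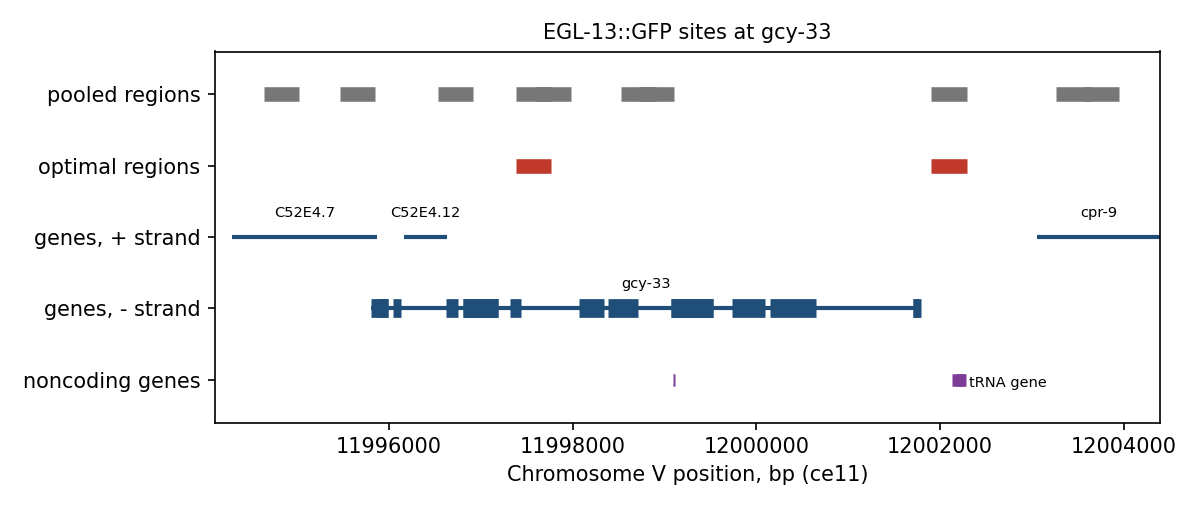
Map of the gcy-33 locus on chromosome V (x axis, ce11 position in bp), with pooled regions in grey, optimal regions in red, protein-coding genes by strand in blue (gcy-33 exons thick) and noncoding genes in purple. The optimal region at 12001906 to 12002289 lies upstream of gcy-33 and covers a tRNA gene, and another optimal region lies inside gcy-33.

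Several large families carried sites less often than other genes. Chemoreceptor genes had them in 5 of 933 cases (odds ratio 0.0555, Fisher's exact adjusted p = 3.87e-28), srh-16 with the strongest, then sri-5, srh-2 and srh-89. Without replicate 3 there were 3 (odds ratio 0.0353). Cuticle collagen genes had them in 3 of 175 (col-71, col-38 and col-63; Fisher's exact adjusted p = 0.00127), Hedgehog-related genes in 1 of 83 (wrt-3; adjusted p = 0.0294), neuropeptide genes in 2 of 102 (flp-17 and flp-19; adjusted p = 0.0323) and nuclear hormone receptor genes in 11 of 269 (nhr-47, nhr-48, nhr-142 and nhr-1 the strongest; adjusted p = 0.0274). Of these 5 lists, chemoreceptors alone were called lower against shifted summits, with a count 0.250 times the shifted mean, a smaller difference than the odds ratio gives. There the ratio for the nuclear hormone receptors was 1.49 and not past the threshold (permutation adjusted p = 0.624). Promoters as a whole held 2.21 times the share of shifted summits, so shifted summits are a lower baseline than other genes. Ratios to shifted summits and odds ratios therefore cannot be set side by side. When each site went to its nearest 5′ end, the neuropeptide call (odds ratio 1.03) and the nuclear hormone receptor call (odds ratio 0.924, 24 genes) ended. The collagen call also ended against genes with any pooled region, and the Hedgehog-related call ended under 6 alternatives. Without replicate 3 the neuropeptide call (5 genes) and the nuclear hormone receptor call ended. The col-63 and flp-17 sites had no replicate 4 summit within 100 bp, and those of wrt-3, flp-19 and srh-89 were below the strongest regions of replicate 4. The col-38 site was also that of the ribosomal protein gene rpl-5.

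The remaining lists did not pass the test, with adjusted p from 0.248 to 1. Heterochronic genes, which time larval development, had sites in 3 of 14 cases (lin-28, lin-14 and lin-46). The lin-28 site had a signal value of 271, with its summit at I:8409919. That lay 1 bp downstream of the nearest annotated 5′ end of a lin-28 transcript, within the gene body (I:8407630-8410804, minus strand). Wnt pathway genes had 4 of 28 (mig-5, wrm-1, lit-1 and pop-1), histones 6 of 50 (with his-37, his-35, his-41 and his-67) and insulin and starvation genes 5 of 54 (with ins-39, hlh-30, ins-14 and daf-16). Among the histones, his-35 and his-41 shared a site, as did his-67 and his-68. Homeobox genes had 5 of 95 (with ceh-38, ceh-54, ceh-23 and ceh-39). A single gene had a site among 17 ciliated neuron genes (daf-19), 24 Q neuroblast genes (pig-1), 30 germline genes (cgh-1) and 18 glia and excretory genes (lit-1). The daf-19 site had no replicate 3 summit within 100 bp, and those of pop-1, lin-14, lin-46, daf-16, his-35 and his-41 were below the strongest regions in 1 replicate. None had one among 5 SOX genes, 18 uterine and anchor cell genes, 21 seam and hypodermis regulators, 31 body wall muscle genes, 19 pharynx genes or 27 intestine genes. None of these 6 lists was long enough to be called lower: for the 31 muscle genes, the longest, 0 sites allow a share of up to 11.2% (exact 95% interval), above the 8.48% of other genes.

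egl-13 itself (WBGene00001182, X:5663837-5674067, plus strand) had no optimal site in its promoter window or body. The nearest optimal summit, at X:5686300, lay 12233 bp from the gene. The gene lies in a stretch of 41151 bp without any pooled summit, against a median of 1884 bp between neighbouring pooled summits, a comparison chosen after seeing the data, so the missing site is not evidence that the factor was absent there.

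A scan of all gene name classes with 15 or more members called 11 classes higher and 13 lower. Ribosomal classes led: 24 of 45 rpl genes and 19 of 31 rps genes had a site (odds ratios 12.5 and 17.3, Fisher's exact adjusted p = 1.14e-12 and 1.12e-11). The lin class, named for cell lineage phenotypes, had sites in 17 of 45 (odds ratio 6.62, Fisher's exact adjusted p = 1.68e-06). Nuclear pore (npp, 10 of 26), DnaJ chaperone (dnj, 10 of 29), heat shock (hsp, 8 of 20), vacuolar sorting (vps, 10 of 31), mitochondrial ribosome (mrpl, 11 of 41), Mediator (mdt, 7 of 20), TFIID (taf, 6 of 17) and cyclophilin (cyn, 5 of 16) classes were also called. The taf call ended without replicate 3 (Fisher's exact adjusted p = 0.344), in the stronger 50% of sites (Fisher's exact adjusted p = 0.0616) and with sites in the top of both replicates (Fisher's exact adjusted p = 0.262). The npp call ended in the last 2 of these (Fisher's exact adjusted p = 0.394 and 0.0936), and the mrpl, mdt and cyn calls each ended under 1 alternative. Lower classes included clec, the C-type lectins, with 1 of 237, and the chemoreceptor classes str, srw and srx with 0 of 190, 109 and 101. The srx call ended in the stronger 50% of sites (Fisher's exact adjusted p = 0.0638), and clec had 2 genes with a site without replicate 3 (odds ratio 0.0967). The number of lower classes fell to between 6 and 8 under alternatives with fewer sites or a narrower window.

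The sequence known for SOX HMG boxes was compared between summits and flanks to ask whether it is centred on the sites. AACAAT lay within 50 bp of 6.15% of summits, less often than in 13.6% of flanking windows 300 bp away (124 sites with it at the summit only, 297 in the flank only, exact McNemar p = 1.81e-17). The difference was −7.43 percentage points, and −4.60 within 25 bp of the summit. Set against 29 other hexamers of the same base composition, AACAAT was not past the threshold. Other A-rich or T-rich sequences were depleted too: TGATAA (4.36% against 9.96%), TGTTTA (5.49% against 8.74%) and TAATTA (3.44% against 5.54%). GAGAGA was the most enriched of the 9 other fixed sequences, at 25.4% of summits against 7.02% of flanks (exact McNemar adjusted p = 1.16e-64). CCGCCC (5.32% against 1.53%), CACGTG (4.27% against 1.70%), TGACGT (6.50% against 3.4%) and CAGCTG (3.36% against 1.68%) were higher as well, with adjusted p from 4.10e-14 to 4.74e-04. TGACTCA did not differ past the threshold (1.18% against 1.00%, exact McNemar adjusted p = 0.551). Among 2080 hexamers merged with their reverse complements, 633 were higher and 493 lower, and GACGCA, at 15.3% of summits against 1.90% of flanks, had the largest ratio of the 10 with the smallest p (7.99 with 0.5 sites added to each count, exact McNemar adjusted p = 3.97e-58); it is named here after its values were seen.

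**Figure D3:**
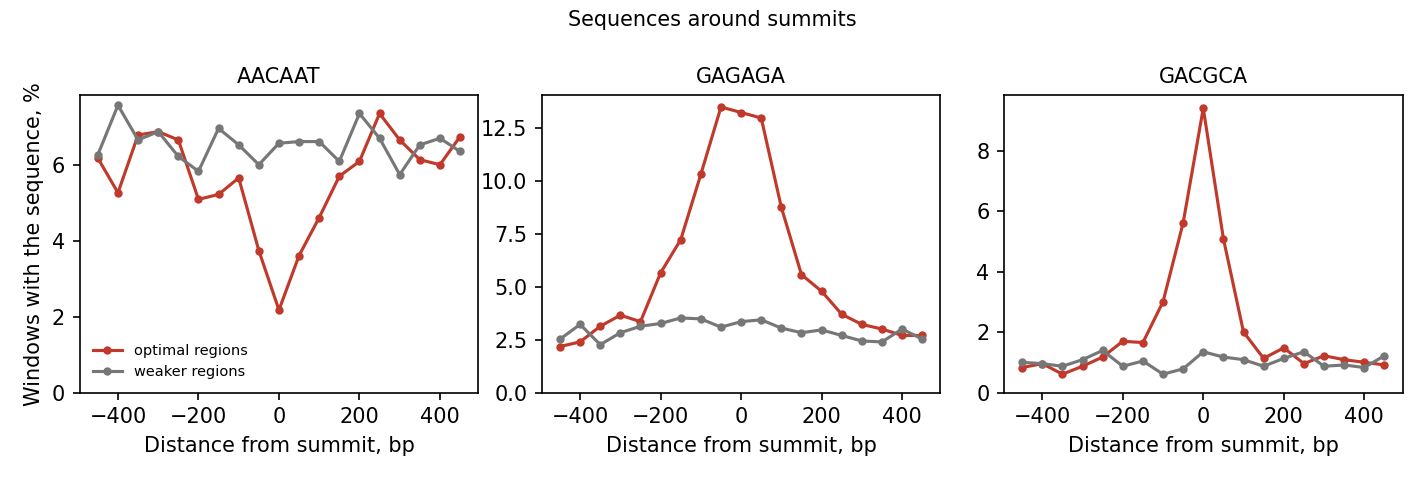
Percent of 51 bp windows with AACAAT, GAGAGA or GACGCA (y axes) against distance from the summit (x axis, bp), for 2294 optimal peaks (red) and 2294 weaker pooled regions (grey). At the summit of optimal peaks AACAAT falls to 2.18%, GAGAGA is at 13.3% and GACGCA at 9.42%.

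Optimal peaks differed from weaker regions of the same libraries. Promoter summits made up 56.8% of optimal peaks against 30.1% of 2294 weaker pooled regions, GC content was 46.1% against 34.9%, GAGAGA lay at 25.4% against 6.06%, and AACAAT at 6.15% against 12.7% (adjusted permutation p = 1e-05 for each, the smallest that 100000 draws can give). Against the regions just below the optimal list the differences shrank, for promoters from 26.7 to 16.3 percentage points, for GC content from 11.1 to 6.0, for GAGAGA from 19.3 to 10.5 and for AACAAT from −6.54 to −2.09. With weaker regions of the same GC content, chosen after seeing the data, AACAAT no longer differed past the threshold (6.15% against 6.41%, permutation adjusted p = 0.904).

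The same libraries were also deposited on ce10, where the optimal list held 2300 regions, against 2294 on ce11. The top optimal signal value, 975, was the same on both. The ce10 list of replicate 3 held 1 region of 700383 bp near the start of chromosome X, and no ce11 region exceeded 562 bp.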

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

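All alternatives were set before the data were examined except the sites in the top of both replicates, GC matching, leaving out sites near tRNA, snoRNA or snRNA genes, the correlation over all pooled regions and the weaker-region comparison within each replicate, which were chosen after seeing the data. Promoter, exon and intron differences, replicate agreement (50.4% to 70.7%), replicate correlation (rho from 0.605 to 0.679), the central autosomal excess and the promoter, GAGAGA and GC differences from weaker regions kept their direction and side of the threshold under every alternative run on them. The counts of fixed motifs and hexamers called higher or lower stayed within a factor of 1.5, which does not show that the same ones were called. No paired analysis was possible because there is 1 group. Replicates were not left out of the agreement and correlation, which need both, or of the optimal list. Unknown read depth limits what a missing site shows.

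With the stronger 50% of sites, 1147 peaks by construction, the X share was 19.5%, classes called lower numbered 6 and intergenic summits lay at 0.843 of chance. The intergenic ratio was 0.963 with sites in the top of both replicates, 0.935 with a 2000 bp promoter window and 1.10, past the threshold, with a 500 bp window. The cause was not tested. Lists called lower numbered 3 to 5 with 1 replicate left out, 3 against genes with any pooled region, 2 with assignment to the nearest 5′ end and 1 against shifted summits. Neuropeptide genes then had an odds ratio of 1.03 under nearest assignment, and nuclear hormone receptors a ratio of 1.49 against shifted summits, a lower baseline than other genes. Classes called lower numbered 7 with sites in the top of both replicates and 8 with a 500 bp window. TGACTCA changed sign, at −0.305 percentage points with the stronger sites and −0.336 with sites in the top of both replicates. AACAAT was −0.264 percentage points against weaker regions of the same GC content, and its summit-to-flank ratio was −0.26 on the log2 scale relative to the median hexamer of the same composition, neither past the threshold. Of 74 genes named for optimal sites, 63 had theirs among the strongest regions of replicate 4 alone and 72 among those of replicate 3 alone.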

Other observations

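All tests in this part except that of AACAAT against hexamers of the same composition were chosen after the patterns they address were seen, including those of noncoding genes, of GC matching, of window length and of motifs at neuronal and ribosomal sites. Sites lay within 200 bp of 95 of 612 tRNA genes, 13.5 times the mean of shifted summits, of 57 of 346 snoRNA genes (13.5 times) and of 13 of 129 snRNA genes (9.45 times). Long intergenic noncoding RNA genes had sites in 17 of 194 cases (2.42 times), a ratio close to the 2.21 of protein-coding promoter windows. Each of these 4 groups had a two-sided permutation adjusted p = 0.003, from 0.002, the smallest p that 1000 shifts can give. MicroRNA genes, at 6 of 261, did not pass the test (permutation adjusted p = 0.216), and of 20 rRNA genes 0 had a site. The 161 optimal sites near tRNA, snoRNA or snRNA genes made up 7.02% of all, and without them 4 fixed lists were still called higher and 5 lower.

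In the lists used here no pooled summit lay between X:5643610 and X:5684761, a stretch of 41151 bp that holds egl-13. It was among the 26 longest of 29994 stretches between neighbouring pooled summits, whose median was 1884 bp. The stretch was 28299 bp in replicate 3 and 37361 bp in replicate 4. Whether the stretch comes from the control alignment, from regions masked in the processing or from the tagged insertion was not tested, so the missing site at egl-13 does not show that EGL-13 was absent there.

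AACAAT was depleted at summits. Base composition may account for this: among 29 other hexamers of the same composition, 6 had a lower summit-to-flank ratio, placing AACAAT at percentile 20.7. With 0.5 sites added to each count, the ratio was 0.454 for AACAAT and 0.541 for the median of the others. No biological explanation was tested, since the design has 1 group.

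GAGAGA was more frequent at optimal peaks than at weaker regions. GC content alone is argued against: with weaker regions of the same GC content the difference was still 13.7 percentage points (25.4% against 11.7%, adjusted permutation p = 2e-05). A hypothesis that stays open is that many regions were recovered without contact of EGL-13 with its own motif, since AACAAT then differed by −0.264 percentage points (permutation p = 0.717), which may equally reflect a motif this hexamer describes poorly. The core ACAAT and the looser form WWCAAWG (W for A or T) were also lower at summits than in flanks, past the threshold. Neither was compared with regions of the same GC content, so base composition may account for that as well. Ribosomal protein sites did not carry GAGAGA more often than other promoter sites (6 of 42 against 282 of 1261, Fisher's exact p = 0.259). An untagged control was not analysed here.

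Sites lay at 19 of 42 pan-neuronal and gas-sensing neuron genes. Longer promoter windows are argued against, since the median window was 1207.5 bp for these genes and 1201 bp for all genes. Random genes matched on window length had 4.84 on average and 1 to 9 in 95% of 10000 draws. These lists were joined after their excess was seen, so the count of 19 is not further evidence of that excess. Whether these are sites of the kind found at ubiquitously expressed genes cannot be told apart with 21 summits: GAGAGA or GACGCA differed by 10.3 percentage points from ribosomal, ATPase and mitochondrial sites (8 of 21 against 15 of 54, interval −11.4 to 33.7, Fisher's exact p = 0.413). The 2 motifs went opposite ways, GAGAGA alone at 8 of 21 against 8 of 54 (p = 0.0558) and GACGCA alone at 0 of 21 against 11 of 54 (p = 0.0282), both by Fisher's exact test and unadjusted. Direct contact through the SOX motif likewise stays open, with WWCAAWG or AACAAT at 1 of 21 summits against 163 of 1282 other promoter summits, −7.95 percentage points (interval −12.3 to 10, Fisher's exact p = 0.503). The prediction written for direct contact before this value was computed, a higher share at these summits, was not met. With 21 summits the interval also holds higher shares, so this does not decide the question.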
